A study of Homo sapiens with 4 samples.

How the data were processed

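The study measured mRNA in NCI-H441 cells, an established human lung adenocarcinoma line, on Affymetrix whole-transcript gene arrays that carry 33252 probe sets. Total RNA was extracted with Trizol and labelled with biotin, and an outside provider did the labelling and hybridization, per the labels' protocols. The 4 samples form 2 groups of 2, cells stably expressing hsa-mir-365-2 and cells with the empty vector, and each sample has 1 array. The labels call the samples of a group biological replicates and do not say whether they came from separate transfections or cultures, so p-values measure the spread between these samples, which may be technical.

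The authors deposited log2 expression values per probe set, made with GCOS and RMA per the submitters' processing notes, which give no versions. RMA corrects the background, quantile normalizes the arrays against one another and summarises the probes of a probe set. The version of the array software, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. The 4 arrays had median log2 values between 7.29 and 7.35 and SDs between 2.23 and 2.26. RMA pulls the arrays towards one distribution, so a shift of most transcripts in one direction would not be seen, and it compresses differences of dim probe sets. A second deposited table holds the log2 values, rounded, of 24 probe sets that the authors call significant. Per the series' design text, these come from a class comparison in BRB Array Tools at a cutoff of 0.001. Its columns were used only as a list: their largest difference from the matching array values after rounding was 0. The number of arrays limits the precision of every value. The files hold no detection calls.

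Gene names came from a table of the platform's annotation. It lists 21214 of the probe sets, 19460 with 1 gene symbol and 1754 with several, and leaves 12038 without a name here. Symbols were brought up to date through gene identifiers in a RefSeq gene table of a recent human assembly, which matched for 19429 probe sets; that table was used for names and for which genes overlap. Each gene was represented by the probe set with the highest mean over all 4 arrays among those with 1 symbol, which left 18417 genes; 769 of them had more than 1 probe set. No gene is named from a probe set with several symbols. Control probe sets carry no names in the files, so they could not be set apart except that they are not among the named genes, and the planned check of RNA quality from their ends was not run.

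The main test was limma (version 3.58.1 in R 4.3.3), a linear model per gene with eBayes moderation, with no block and no filter on dim genes. It was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 18417 genes; the threshold was 0.05. Counts at an unadjusted p under 0.001, the submitters' own cutoff, are given beside it. Differences are miR-365-2 minus empty vector on the log2 scale, with the moderated standard error. With 2 arrays against 2, an exact permutation test of 1 gene cannot go below a two-sided p of 0.333, so none was used.

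The 22 gene lists, the rule for named genes and the alternatives were written before the data were examined. The rule took up to 12 genes in each direction with the largest difference among those past the threshold. Where too few passed, it was filled with genes at an unadjusted p under 0.001 whose 2 groups did not overlap, to be given as values and not as changes. It added NKX2-1, up to 4 members of each list with the smallest p, and every gene on the deposited list. HMGA2, which the rule also names, shares its probe set with another gene, so no value is given for it. Lists came from general knowledge of the pathways and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists. Of 443 list entries, 36 had no probe set of their own among the genes tested. Camera with an estimated correlation and limma's fry were alternatives, and camera on ranks was added after the data were seen. With an estimated correlation, camera uses only the 2 residual degrees of freedom of the fit, so a list can hardly pass whatever its correlation.

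The other alternatives were the mean of all probe sets of a gene, all probe sets without collapse, a minimum mean log2 of 5 or 6, repeated quantile normalization, centring on array medians, eBayes with a trend or with robust settings, the replicate number as a block, an equal-variance test per gene, a minimum fold of 2, and leaving out each array. Where an array was left out, its group held a single array, assumed to vary like the other group. A setting that drops probe sets by the suffix of their name was not run because these names have none, and a test of miR-365 seed sites was not run because no 3' UTR sequence was used here.

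The limma step was tested on simulated arrays built from the means and spread of these 18417 genes with 200 genes changed. Without a shared replicate effect it recovered 23.9% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 3-fold, with 8 false calls. With the replicate effect estimated from these arrays added, the shares were 5.97%, 89.6% and 100%, with 0 false calls. The adjustment is more lenient the more genes change, and how many change in the real arrays is unknown. There the 3 genes that differed by at least 2-fold did not pass, so these shares are not the power of the test in these data.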

Results

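The arrays addressed what enforced expression of hsa-mir-365-2, one of the genomic copies of the microRNA miR-365, did to mRNA levels in NCI-H441 cells. NCI-H441 is a lung adenocarcinoma line that keeps features of distal lung epithelium, among them expression of the lung transcription factor NKX2-1. Stable miR-365-2 expressors (n = 2 arrays) were compared with empty-vector cells (n = 2 arrays). Over all probe sets, Pearson correlations between pairs of arrays lay between 0.993 and 0.996. The highest were between same-numbered arrays of different groups (0.9963 and 0.9956), above those within the miR-365-2 group (0.9944) and the empty-vector group (0.9936). The overexpressed precursor itself was not analysed here. The probe set of the other genomic copy, MIR365A, read 6.18 ± 0.02 with miR-365-2 and 6.12 ± 7.6e-04 with empty vector (log2, mean ± SD, n = 2), which says nothing about the transgene.

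Differences between the 2 cell populations were small. The largest were lower levels with miR-365-2 of the immediate-early transcription factors FOSB and FOS, at 3.02-fold and 2.80-fold, and of the microRNA-21 precursor MIR21 at 2.18-fold. These were also the 3 genes that differed by at least 2-fold, and none was higher by that much. No gene passed an adjusted p of 0.05 by limma among 18417 genes, and the smallest adjusted p was 0.228. At an unadjusted p under 0.05 limma gave 658 genes, against 921 expected by chance. An equal-variance test per gene gave 0 genes after adjustment and 971 before it. The 658 became 1164 with eBayes with a trend in the variance and 2406 with the replicate number as a block. The fit without a block leaves in its error what same-numbered arrays share, so its count under chance does not show that few genes differ. After adjustment limma called 110 genes with that trend and 99 with that block, though the labels do not say that equal numbers mark a pair. Leaving out an array also moved the count, but such a fit takes in part of the difference between the replicate numbers. At the submitters' cutoff of 0.001 limma gave 34 genes, 10 higher and 24 lower, where chance would give 18.4. That count was 167 with the trend, 196 with the replicate number as a block and 14 by the equal-variance test. The 2 groups did not overlap in 30.7% of all genes, where chance gives 33.3% if same-numbered arrays share nothing. Single genes are therefore given as values, whose differences did not pass the threshold over all genes in the main test.

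The leading lower genes included immediate-early genes and targets of ATF4, none of which passed over all genes. FOSB read 8.22 ± 0.23 with miR-365-2 and 9.82 ± 0.19 with empty vector (log2, mean ± SD, n = 2), a difference of -1.60 ± 0.14 (SE). FOS, like FOSB a subunit of the AP-1 transcription factor, differed by -1.49 ± 0.15, the zinc-finger factor EGR1 by -0.84 ± 0.12, and the MAP kinase phosphatase DUSP1 by -0.81 ± 0.14. CHAC1, an enzyme that degrades glutathione, differed by -0.95 ± 0.10 from 9.98 ± 0.13 with empty vector, and asparagine synthetase ASNS by -0.77 ± 0.09. Both are known targets of the transcription factor ATF4, whose own difference was -0.65 ± 0.10; a second, dimmer ATF4 probe set gave -0.29. The smallest limma adjusted p among these 7 genes was 0.228 and the largest 0.468. MIR21 differed by -1.12 ± 0.16, whereas VMP1, the gene whose span contains MIR21, differed by -0.06 ± 0.10. Of the microRNA precursors 104 of 173 were lower with miR-365-2 (median -0.03), and of the small nucleolar and nuclear RNAs 110 of 195 (median -0.04), but both classes differed more between replicate 2 and replicate 1, in opposite directions (medians of -0.11 and 0.13). The other leading lower genes were the cytokine receptor subunit IL20RB (-0.75 ± 0.11), the pore-forming protein gene GSDMB (-0.65 ± 0.10), the U1 small nuclear RNA variant RNVU1-15 (-0.87 ± 0.12, and -0.88 at a second probe set), which belongs to a family of near-identical genes, and the dim read-through gene KLRC4-KLRK1 (-0.83 ± 0.10), which overlaps another gene and belongs to a family of similar sequence.

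Of the 10 leading higher genes, 4 are on the fixed list of hypoxia and glycolysis genes. PFKFB4 and PFKFB3, kinases that stimulate glycolysis, differed by 0.80 ± 0.10 and 0.58 ± 0.09 (log2, SE, n = 2 per group). PFKFB4 read 8.72 ± 0.11 with miR-365-2 and 7.92 ± 0.03 with empty vector. ANGPTL4, a secreted inhibitor of lipoprotein lipase, differed by 0.70 ± 0.09, and PDK1, the pyruvate dehydrogenase kinase that diverts pyruvate from mitochondria, by 0.57 ± 0.09. The others were LRRC4 (0.72 ± 0.09), FAM162A (0.58 ± 0.10), POFUT4 (0.57 ± 0.10), MIX23 (0.53 ± 0.09), the cornified envelope gene SPRR1A (0.54 ± 0.09) and the pseudogene RPL23P8 (0.54 ± 0.09), whose probes can pick up its parent gene. Limma adjusted p-values of the 10 genes ran from 0.282 to 0.468.

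**Figure D1:**
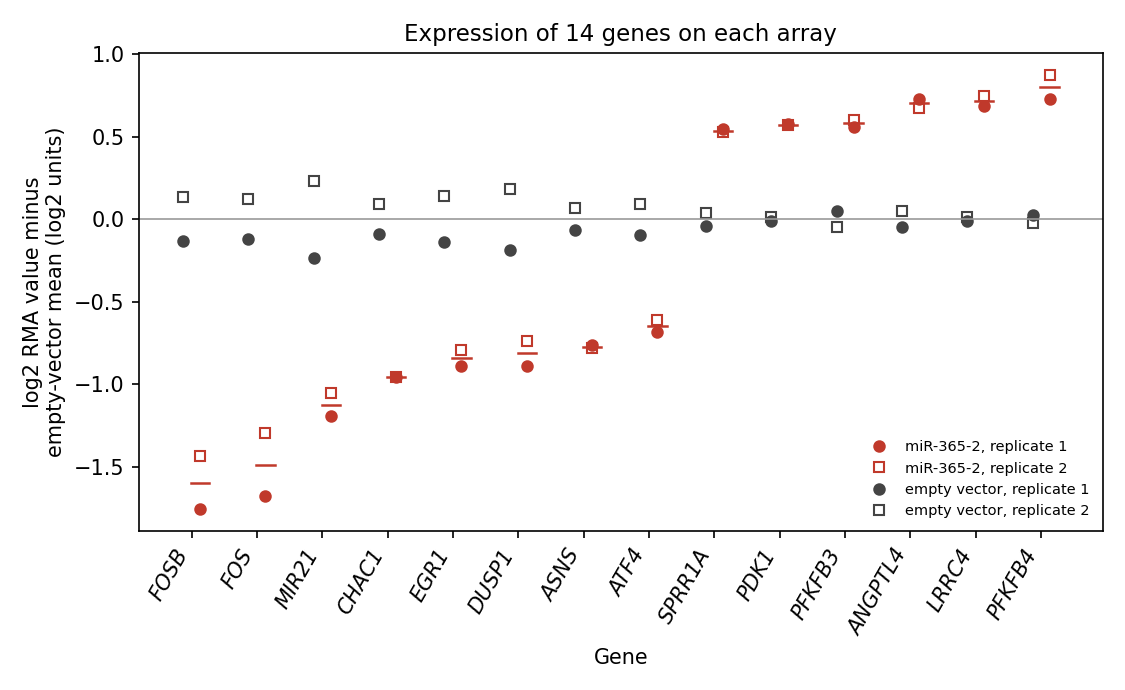
Expression on each array of 14 genes named in the text, as the log2 RMA value minus the mean of the 2 empty-vector arrays (vertical axis, log2 units). Grey points are empty-vector arrays and red points miR-365-2 arrays, circles and squares are replicates 1 and 2, and red bars are miR-365-2 means, which run from -1.60 for FOSB to 0.80 for PFKFB4.

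The mRNAs of genes known from the literature as miR-365 targets, among them NKX2-1, did not pass the set test. Neither did the list of NKX2-1 and distal lung lineage genes. Protein was not measured and the overexpressed precursor was not analysed, so this is no evidence against targeting. NKX2-1, which encodes TTF-1, read 10.70 ± 0.01 with miR-365-2 and 10.54 ± 0.08 with empty vector (log2, mean ± SD, n = 2). Its difference was 0.16 ± 0.09 (SE), with a 95% interval from -0.06 to 0.37 and a limma adjusted p of 1.00. Of 13 measured targets, 6 were higher and 7 lower, with a mean difference of 0.03 and a median of -0.02 (camera adjusted p = 0.837). None passed over all genes, and 1 passed when adjusted over the list alone, the cytokine IL6, which was higher by 0.50 ± 0.10. The kinase SGK1 (-0.14 ± 0.09), the phosphatase CDC25A (0.14 ± 0.10) and the deacetylase HDAC4 (-0.10 ± 0.10) lay within 2 standard errors of 0. Of 24 NKX2-1 and distal lung genes, 13 were higher and 11 lower, with a mean of 0.01 (camera adjusted p = 0.907), and 0 passed over all genes or when adjusted over the list alone. The members with the smallest p were MYBPH, a reported NKX2-1 target (0.34 ± 0.10), the ETS factor ETV5 (-0.28 ± 0.09), NKX2-1 itself and the secretoglobin SCGB3A2 (0.13 ± 0.13), whose sign turned without empty vector replicate 2 (-0.03). The sign of this list's mean turned to -0.04 without miR-365-2 replicate 1 and to -0.03 without empty vector replicate 2.

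The hypoxia and glycolysis genes rose as a set. Of 19 measured, 16 were higher, and the mean difference was 0.26 ± 0.06 (log2, SE over genes), with a median of 0.24 (camera adjusted p = 1.5e-12). With an estimated correlation the call was lost (adjusted p = 0.325). The estimate for this list was -0.04, below the preset 0.01, so correlation between its genes is not what removed the call. None passed over all genes, and 7 passed when adjusted over the list alone, all higher: PFKFB4, ANGPTL4, PDK1, PFKFB3, the mitophagy gene BNIP3 (0.39), the oxygen-sensing prolyl hydroxylase EGLN3 (0.32) and the glucose transporter SLC2A1 (0.29). The hypoxia target VEGFA was lower by value (-0.22 ± 0.09). The call was kept without each array in turn and by fry (adjusted p = 0.0461).

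The ERK pathway output genes fell as a set, with a mean difference of -0.19 ± 0.08 (log2, SE over genes) and 16 of 20 lower (camera adjusted p = 9.2e-06). With an estimated correlation, which was 0.31 for this list, the call was lost (adjusted p = 0.649). None passed over all genes, and 2 passed when adjusted over the list alone, FOS and EGR1, which respond to many signals besides ERK. ETV5, PHLDA1 (-0.26 ± 0.09) and ETV1 (-0.30 ± 0.12) were lower by value, while the feedback phosphatases DUSP6 (-0.07) and DUSP4 (0.08) lay near 0. Without FOS and EGR1, a setting chosen after seeing the data, the mean was -0.09. The call was kept without each array in turn and was lost by fry (adjusted p = 0.261).

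The unfolded protein response list fell as a set (camera adjusted p = 0.0369), and its members went in opposite directions. With an estimated correlation, which was 0.17 for this list, the call was lost (adjusted p = 0.685). Its mean was -0.13 ± 0.08 (log2, SE over genes) and its median 0.02, with 11 of 20 higher and 9 lower. None passed over all genes, and 5 passed when adjusted over the list alone, all lower: CHAC1, ASNS, ATF4, the phosphatase regulator PPP1R15A (-0.52) and the transcription factor DDIT3 (-0.50). These belong to the ATF4 arm, which amino acid shortage also drives. The endoplasmic reticulum genes CRELD2 (0.28 ± 0.10), SDF2L1 (0.24 ± 0.09) and DNAJC3 (0.17 ± 0.09) were higher by value. The call was lost without empty vector replicate 2 (mean -0.09) and by camera with the replicate number as a block (adjusted p = 0.112). It was also lost by fry (adjusted p = 0.261) and by camera on ranks (adjusted p = 0.916), a setting chosen after seeing the data.

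The other 4 lists called by camera had smaller mean differences than the hypoxia and ERK lists. With an estimated correlation all 4 calls were lost (camera adjusted p = 0.649 for each). The estimates were 0.17 for cholesterol synthesis and 0.16 for G1/S genes, above the preset 0.01. For squamous (-0.05) and mesenchymal genes (0.0062) they lay below it. Cholesterol synthesis genes rose as a set, with 14 of 16 higher and a mean of 0.12 ± 0.02 (log2, SE over genes, adjusted p = 2.7e-04), among them SC5D (0.25), IDI1 (0.22), LSS (0.22) and DHCR7 (0.20). G1/S cell cycle genes rose as a set, with 23 of 25 higher and a mean of 0.09 ± 0.01 (adjusted p = 2.7e-04), among them the replication factor GINS2 (0.24), the ribonucleotide reductase subunit RRM2 (0.22), the histone mRNA binder SLBP (0.16) and the cyclin CCND3 (0.17). None of either list passed over all genes or when adjusted over the list alone. Squamous and basal cell genes rose as a set (mean 0.17 ± 0.08, 9 of 12 higher, adjusted p = 0.0042). The 3 that passed when adjusted over the list alone were the cornified envelope genes SPRR1B (0.78 ± 0.15), SPRR1A and SPRR3 (0.33 ± 0.09), with SPRR2A at 0.31 ± 0.13, whereas the basal keratins KRT5 (-0.07) and KRT14 (-0.13) lay within 1 standard error of 0. Mesenchymal genes fell as a set (mean -0.07 ± 0.03, 16 of 23 lower, adjusted p = 0.0192), and 1 passed when adjusted over the list alone, the receptor kinase AXL (-0.51 ± 0.09). The mean of this list was -0.01 without empty vector replicate 1 and -0.13 without empty vector replicate 2. The filament gene VIM (-0.28 ± 0.09), the collagen cross-linking enzyme LOX (-0.23 ± 0.10) and the smooth muscle actin ACTA2 (-0.18 ± 0.09) were lower by value. By fry all 4 calls were lost (adjusted p = 0.261 for cholesterol synthesis, 0.276 for G1/S, 0.251 for squamous and 0.663 for mesenchymal genes), by camera on ranks the squamous (0.210) and mesenchymal calls (0.0830), and with repeated quantile normalization the mesenchymal call (0.0510). Without miR-365-2 replicate 2 the calls were lost for cholesterol synthesis (mean 0.09), G1/S (0.06) and mesenchymal genes (-0.05). The mesenchymal call was also lost without miR-365-2 replicate 1 (mean -0.09) and without empty vector replicate 1. Without empty vector replicate 2 the squamous call was lost (mean 0.15).

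**Figure D2:**
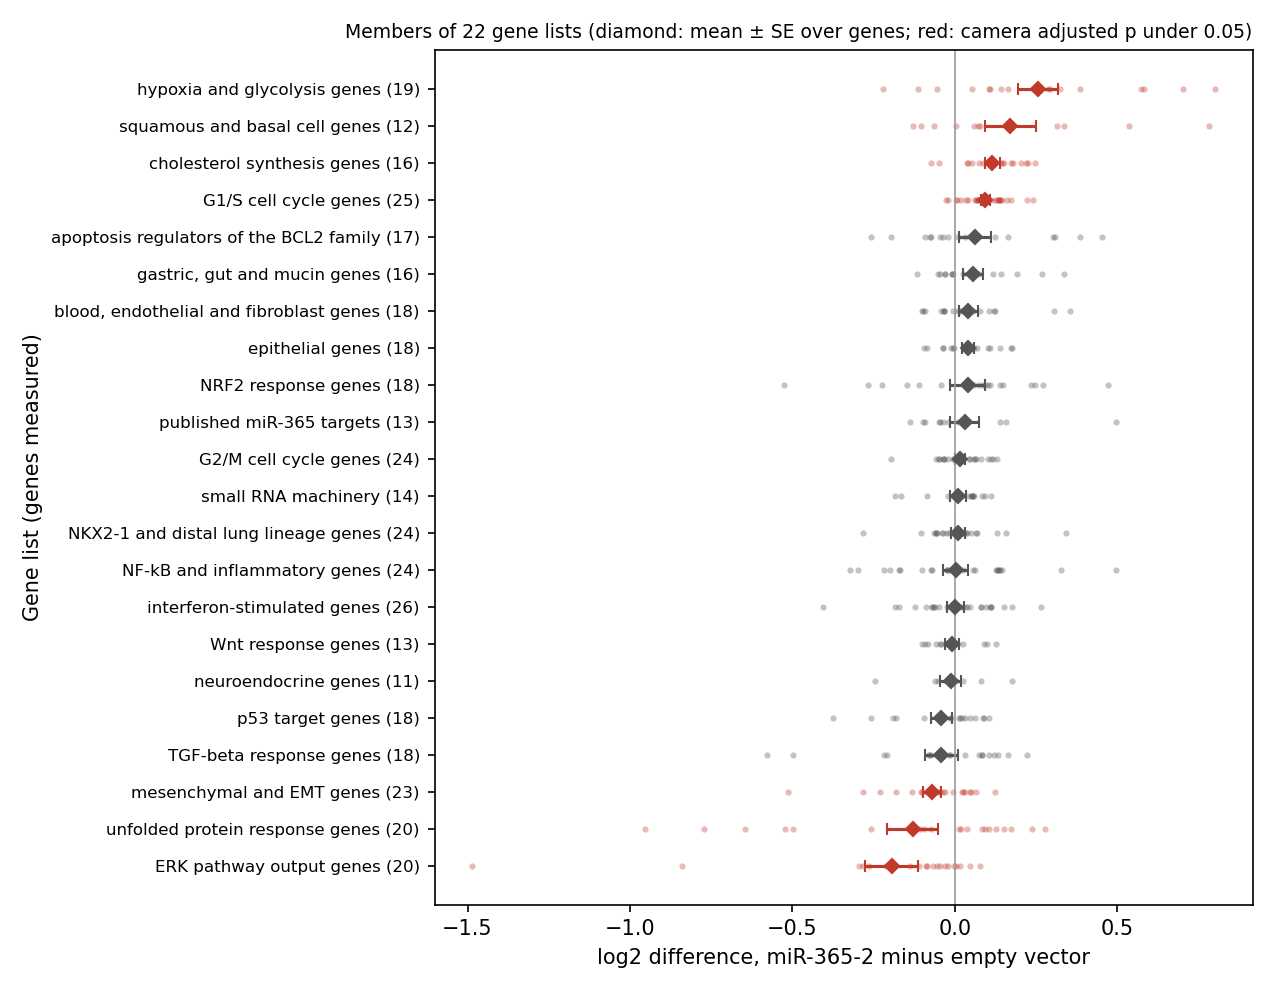
Log2 difference, miR-365-2 minus empty vector (horizontal axis), of every measured member of the 22 gene lists (small points), with the mean and SE over genes of each list (diamond and bar) and the number of genes measured in brackets. Red marks the 7 lists with a camera adjusted p under 0.05, from hypoxia and glycolysis with a mean of 0.26 to ERK pathway output with -0.19.

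The other 13 lists did not pass camera (0 to 2 members of each passed when adjusted over the list alone, and none over all genes). Markers of blood, endothelial and fibroblast cells had a mean of 0.04 (10 of 18 higher, adjusted p = 0.481), with 0 passing when adjusted over the list alone. The highest were lysozyme, LYZ (0.35 ± 0.11), and the receptor KDR (0.30 ± 0.12), and CDH5 (0.10 ± 0.11) and DCN (-0.10 ± 0.11) turned sign without miR-365-2 replicate 1 (-0.0013) and empty vector replicate 1 (0.04). Epithelial genes had a mean of 0.04 (11 of 18 higher, 0.257), with the transcription factors OVOL1 (0.18 ± 0.09) and ELF3 (0.17 ± 0.09), the keratin KRT19 (0.14 ± 0.09) and the splicing regulator ESRP2 (0.11 ± 0.09) at its top. Gastric, gut and mucin genes had a mean of 0.06 (8 of 16 higher, 0.257), among them the goblet cell factor SPDEF (0.34 ± 0.10), AGR2 (0.27 ± 0.10) and the mucins MUC13 (0.19 ± 0.12) and MUC1 (0.14 ± 0.09). Neuroendocrine genes had a mean of -0.01 (4 of 11 higher, 0.812), from SCG2 (-0.25 ± 0.10) to CHGA (0.18 ± 0.13), both granins, with NCAM1 (0.08 ± 0.12) and UCHL1 (-0.05 ± 0.10) between them. NCAM1 turned sign without empty vector replicate 2 (-0.09) and UCHL1 without empty vector replicate 1 (0.03). Without empty vector replicate 1 the mean was 0.11 for the blood, endothelial and fibroblast list and 0.12 for the gastric list. The neuroendocrine mean was -0.13 without empty vector replicate 2 and 0.10 without empty vector replicate 1. These contrasts take in part of the difference between the replicate numbers. The epithelial list passed camera with the trend (adjusted p = 0.0487).

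Among the cell cycle, apoptosis and signalling lists, 0 members passed when adjusted over the list alone except where named. G2/M genes had a mean of 0.01 (13 of 24 higher, adjusted p = 0.812), with the mitotic kinases BUB1 (-0.20 ± 0.09) and PLK1 (0.11 ± 0.09), the kinesin KIF11 (0.13 ± 0.09) and the cyclin CCNB1 (0.10 ± 0.10). The p53 targets had a mean of -0.04 (9 of 18 higher, 0.257). The lowest by value were the stress gene SESN2 (-0.38 ± 0.10), PMAIP1 (-0.26 ± 0.10), the death receptor TNFRSF10B (-0.19 ± 0.09) and GDF15 (-0.18 ± 0.12). The mean of this list was -0.07 without empty vector replicate 1. BCL2 family genes had a mean of 0.06 (9 of 17 higher, 0.257), with BCL2A1 (0.45 ± 0.12), BNIP3, BID (0.31 ± 0.09) and BIK (0.30 ± 0.09). Interferon-stimulated genes had a mean of 5.0e-04 and a median of 0.02 (15 of 26 higher, 0.852), with camera's direction down. Their members with the smallest p were IFI44L (-0.41 ± 0.10), IFI6 (-0.17 ± 0.09), ISG20 (-0.19 ± 0.10) and ISG15 (0.17 ± 0.10). NF-kB and inflammatory genes had a mean of 0.0025 and a median of -0.02 (11 of 24 higher, 0.959), with IL6, the acute phase gene SAA2 (-0.32 ± 0.11), the chemokine CCL20 (0.33 ± 0.15) and IL1B (-0.22 ± 0.10).

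TGF-beta response genes had a mean of -0.04 and a median of 0.01 (9 of 18 higher, adjusted p = 0.663), and a mean of -0.07 without miR-365-2 replicate 2. The matricellular protein gene CCN2 passed when adjusted over the list alone (-0.58 ± 0.10), with CCN1 (-0.50 ± 0.13), TGFB2 (-0.22 ± 0.10) and ID1 (0.22 ± 0.10) beside it as values. Wnt response genes had a mean of -0.01 (5 of 13 higher, 0.852), with the inhibitor DKK1 (0.13 ± 0.09), the ubiquitin ligases RNF43 (0.10 ± 0.09) and ZNRF3 (0.09 ± 0.09) and NKD1 (-0.10 ± 0.12), which turned sign without empty vector replicate 1 (0.0043). NRF2 response genes had a mean of 0.04 (12 of 18 higher, 0.257), and 2 passed in opposite directions when adjusted over the list alone, the cystine transporter SLC7A11 (-0.53 ± 0.11) and the glutathione synthesis enzyme GCLC (0.47 ± 0.11). The transporter ABCC3 (-0.27 ± 0.09) and GCLM, the partner subunit of GCLC (0.27 ± 0.12), followed. The small RNA machinery had a mean of 0.01 (9 of 14 higher, 0.852), with AGO3 (-0.18 ± 0.10), AGO4 (-0.17 ± 0.09), RAN (0.11 ± 0.10) and TARBP2 (0.09 ± 0.10) as its members with the smallest p. Without empty vector replicate 1 the means of the G2/M (-0.02), interferon (-0.03), NF-kB (-0.0094), small RNA machinery (-0.03) and Wnt lists (0.04) turned sign. All of these but NF-kB also turned without miR-365-2 replicate 2, and NF-kB without miR-365-2 replicate 1.

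The authors' deposited table lists 24 probe sets as significant. In a limma fit over all probe sets, 16 of them were lower and 8 higher with miR-365-2. Of the 24, 9 had 1 gene symbol (FOSB, FOS, CHAC1, ASNS, EGR1, MIR21, RNVU1-15 and KLRC4-KLRK1, lower by value, and PFKFB4, higher), 2 had several symbols and 13 have no gene name here. Limma over all probe sets gave an unadjusted p under 0.001 to 16 of the 24 and to 7 further probe sets. Of the 24, the equal-variance test gave such a p to 2. None had a limma adjusted p under 0.05, each being 0.851.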

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

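The Fisher's exact tests in this part, and the run of probe sets the second one is on, were chosen after the list had been seen, and the test of spread was set before its result was computed. The authors' deposited table of 24 significant probe sets includes 13 that have no gene name here, data that the gene comparisons do not use. Such probe sets make up 54.2% of the deposited list and 36.2% of the array (two-sided Fisher's exact test p = 0.0875, odds ratio 2.08). Of the 13, 12 belong to a run of 4158 probe sets whose identifiers all precede the first one in the annotation. That run makes up 12.5% of the array and 50% of the deposited list (two-sided Fisher's exact test p = 9.0e-06, odds ratio 7.01). The differences of the 12 ranged from 0.73 to 1.32 in absolute log2 units, at mean log2 levels from 4.48 to 7.53 (median of the run 7.42). At matched mean level, the median SD within groups of the run was 2.33 times that of the named probe sets, and between 1.74 and 3.45 times over bins of level. At an unadjusted p under 0.001, limma over all probe sets gave 12 of the run, where 4.16 are expected by chance, and 10 of the named probe sets, where 21.2 are expected. A larger spread is therefore a candidate explanation for their share of the list. Whether some follow a real transcript stays open without their sequences, and no biological explanation was tested.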

How the results depend on the processing

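Camera on ranks, the probe sets in the annotation without collapse to genes, the lists without FOS and EGR1 and the split of the unfolded protein response list were chosen after the data were seen, all other settings before. The count of 0 genes at an adjusted p under 0.05 was the same with the mean of all probe sets of a gene, all probe sets, probe sets in the annotation, both dim filters, repeated quantile normalization, centring, robust eBayes, a minimum fold of 2, and the equal-variance test. It moved to 110 with eBayes with a trend, to 99 with the replicate number as a block (30 higher and 69 lower), and to between 0 and 34 when 1 array was left out. The 34 genes at an unadjusted p under 0.001 became 167 with the trend, 196 with the block, 14 in the equal-variance test, of which 1 was among the 34, and between 31 and 74 without 1 array; 33 of the 34 were among the 167 and all 34 among the 196. The 7 called lists became 0 with an estimated correlation and 1 by fry, and 4 by camera on ranks, which lost the unfolded protein response (adjusted p = 0.916), squamous (0.210) and mesenchymal calls (0.0830); under the block the unfolded protein response list lost its call (adjusted p = 0.112) and no other list call changed, and repeated quantile normalization ended the mesenchymal call (adjusted p = 0.0510). The cause of these moves was not tested, except that the block leaves fewer residual degrees of freedom and takes out what same-numbered arrays share. Those arrays deviated together (correlation of deviations from the group means 0.562), and the source names also carry the letters A and B, 1 letter per number. The labels do not say whether number or letter marks a shared transfection, culture or day, so no pairing was assumed, and whether the arrays are paired stays open. Split by that number the 4 arrays gave 146 genes at an unadjusted p under 0.001, split by group 34, and by the crossed split 2, which points to a structure of the samples. In simulated arrays with such a shared effect the block fit recovered 100% of genes changed 1.5-fold, 2-fold and 3-fold, 200 in all, with 52 false calls. That is a larger share of false calls than a threshold of 0.05 allows, so the 99 calls with the block may hold more false ones than that threshold implies. Of the named genes, 29 passed an adjusted p of 0.05 with the block and 34 with the trend. No named gene turned its sign outside the settings that leave out an array. There, among values near 0, the ranges were -0.0013 to 0.21 for CDH5, -0.14 to 0.0325 for UCHL1, -0.24 to 0.0366 for DCN, -0.21 to 0.0043 for NKD1, -0.0280 to 0.29 for SCGB3A2 and -0.0852 to 0.24 for NCAM1. Lists that did not pass camera and turned the sign of their mean were neuroendocrine genes (0.0078 at a mean log2 of at least 6, 0.0077 with repeated quantile normalization, 0.0080 with centring), interferon genes (-0.0085 at a mean log2 of at least 6), G2/M genes (-0.0069) and the small RNA machinery (-8.7e-04) with repeated quantile normalization, and Wnt genes (0.0118 with centring). Without 1 array their means and those of other uncalled lists ranged from -0.0402 to 0.0584 (NKX2-1 and lung genes), -0.0043 to 0.12 (gastric), -0.13 to 0.10 (neuroendocrine), -0.0246 to 0.11 (blood, endothelial and fibroblast), -0.0199 to 0.0489 (G2/M), -0.0303 to 0.0313 (interferon), -0.0094 to 0.0144 (NF-kB), -0.0623 to 0.0424 (Wnt) and -0.0257 to 0.0440 (small RNA machinery). The 12 unfolded protein response genes outside the ATF4 arm, set apart after seeing the data, had a mean of 0.0817. Centring on array medians moved the median of all genes from 0.0050 to 0.03. Under robust eBayes no lists were tested, since camera has no such option. The check of RNA quality, the seed site test and the suffix setting were not run. The signal over background of single probe sets is unknown, which limits what can be said of dim genes.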

Other observations

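The tests on single array pairs, probe set brightness and culture state were chosen after the result was seen; so were the test on host genes, the restriction to genes outside every fixed list, and the lists of further genes, which were drawn up once the leading genes and the fixed lists had been seen. Percentiles against random lists take no account of correlation between genes. Of 18 immediate-early genes that were neither among the leading ones nor on the ERK list, 15 were lower with miR-365-2, with a mean log2 difference of -0.14 against a 5th percentile of -0.04 for 10000 random lists matched on level (percentile 0.03). Their median of -0.09 lay closer to 0, and 9 of the 18 lay within 1 SE of 0, so part of the members carried the mean. Outside every fixed list 12 of 15 were lower (percentile 0.05, median -0.08). The lowest of the 18 were RHOB (-0.39 ± 0.10, SE), KLF6 (-0.38 ± 0.13), NR4A2 (-0.34 ± 0.16), KLF4 (-0.33 ± 0.10) and IER2 (-0.30 ± 0.09). Of 25 further genes of the ATF4 amino acid response, 21 were lower, with a mean of -0.19 (percentile 0, so below all random lists), a median of -0.22 and 6 within 1 SE of 0, as were 19 of the 23 outside every fixed list (percentile 0). They included the tRNA synthetases SARS1 (-0.38 ± 0.09), MARS1 (-0.35 ± 0.09) and AARS1 (-0.32 ± 0.09) and the amino acid transporters SLC7A5 (-0.25 ± 0.09) and SLC1A5 (-0.22 ± 0.09). Of 19 endoplasmic reticulum chaperone genes 17 were higher, with a mean of 0.08 (percentile 99.7), but this list shares genes with the fixed ones. Of the 8 outside every fixed list 7 were higher, and their mean of 0.07 lay within the range of random lists (percentile 91.3). A lower mean of immediate-early and of ATF4 target genes is therefore a hypothesis that held on members not used to form it, in the same 4 arrays. A fall of the whole immediate-early class is not shown. No label separates the culture dish from the group. Whether either pattern follows from miR-365-2 or from the state of the dishes at harvest therefore cannot be told apart.

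The camera call of the hypoxia and glycolysis genes was lost with an estimated correlation (adjusted p = 0.325), an estimate of -0.04 that lies below the preset 0.01. Their rise is still the first pattern to follow up. A single pair of arrays does not carry it: the mean difference was 0.267 between the arrays numbered 1 and 0.243 between those numbered 2. Brightness of the probe sets does not account for it either, since the mean exceeded all 10000 random lists matched on level (percentile 100). A wider oxygen response is consistent with the data: of 27 other oxygen-responsive genes 25 were higher, with a mean of 0.18 (percentile 100), and 24 of the 26 outside every fixed list (percentile 100), among them the glycogen enzyme GBE1 (0.45 ± 0.10, SE) and the oxygen sensor EGLN1 (0.28 ± 0.09). Whether this follows from miR-365-2 or from the state of the dishes at harvest, such as density or the age of the medium, cannot be told apart, because 0 labels separate the dish from the group.

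Small nucleolar and nuclear RNAs form the second pattern, as 110 of 195 were lower with miR-365-2, with a median of -0.04, below all random lists of other genes matched on level (percentile 0). Of genes that are neither these nor microRNA precursors, 8663 of 18049 were lower. A difference in the recovery of small RNAs may explain the lower median of the class. The class also differed between the replicate numbers by more, a median of 0.13 higher in replicate 2 (146 of 195 genes higher). The microRNA precursors, of which 104 of 173 were lower with miR-365-2 (median -0.03, percentile 4.8), were lower in replicate 2 (median -0.11, 49 of 173 higher). A single shift of all small RNAs therefore does not describe the difference between replicate numbers. Between the groups both classes were lower with miR-365-2, so a shared shift there stays open. A fall in host mRNA is argued against for the 82 of 175 small nucleolar RNAs with a measured host. Of these 82, 53 were lower, with a median of -0.11, below the class median of -0.04. Their 62 hosts had a median of 0.0313 (SD 0.08), with 25 hosts lower. A host was the smallest measured gene whose span contains the RNA, whatever its strand. The arrays read mRNA levels and not transcription, so lower transcription of the hosts stays open. The 93 without a measured host were not tested apart, so whether they were lower as a group is not shown. A fall in the mRNA of their hosts stays open as well, and a change in the processing of these RNAs was not tested.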
